A study of Mus musculus with 18 samples.

How the data were processed

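RNA of whole jejunum from 18 libraries (6 control, 5 CONV, 7 FLASH) was sequenced after stranded mRNA ligation library preparation from 250 ng of RNA, as single-end reads of 100 bp. Groups and replicate numbers were taken from the labels. Per the labels, the authors aligned reads with STAR and quantified them with Salmon on mm10 (versions not stated), and named edgeR 3.40.2 and limma 3.54.2 for later steps.

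The deposited count table held expected counts (estimated read counts per Ensembl gene, not scaled) for 54532 genes. Per library, 59.1 to 62.4% of its values were 0, and 73.3 to 76.9% of the others were whole numbers. All were rounded before use. The second deposited table held log2 values that the authors had normalized, for 19193 genes, 605 of which had 0 counts in every library. From both tables, these values equalled log2 CPM with 1 effective library size per library. The annotation gave a symbol for 54409 gene IDs and none for 123, which held 0.028% of counts. Coordinates are mm10.

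The main test was the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) with all 18 libraries in 1 fit, filterByExpr, TMM factors, robust dispersion and Benjamini-Hochberg adjustment over 16257 genes, with a threshold of 0.05. Positive log2 fold changes mean higher in the first group named. Errors of log2 fold changes are standard errors derived from the test, as the absolute log2 fold change over the square root of its F statistic. CPM (estimated counts scaled to a common library size) use TMM-scaled library sizes. Of 44 gene lists, 42 had at least 5 measured members and were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2. The exocrine pancreas list (4 measured) and the sex-linked list (1 measured) were not tested. Each list was also tested by camera with an estimated correlation, by fry, and by a two-sided exact permutation of its mean log2 CPM per library, adjusted over lists.

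The comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named per comparison were the 10 risen and 10 fallen genes with the largest changes among those that passed, with a mean of at least 5 CPM in the higher group, no overlap between groups and a symbol that is not a predicted model. Up to 4 members of each list with the smallest p were also named, and Cdkn1a, Mdm2, Mki67, Lgr5, Olfm4, Clu, Pecam1, Kdr, Plvap and Vwf in every comparison.

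The alternatives fixed in advance were a log2 fold change over 1, DESeq2 size factors, library totals, TMM without the 50 most abundant genes, a filter of at least 1 count or a mean of 1 CPM, the genes of the authors' table, DESeq2 1.42.0, limma-voom, limma-trend on the authors' log2 values, fits of only the groups compared, a block on replicate number, 1 surrogate variable (sva 3.50.0) and leaving out each library. Alternatives chosen after seeing the data were an offset for transcript length and GC content (a spline with 4 degrees of freedom per library), leaving out control 6, CONV 6 and FLASH 1 together, and leaving out FLASH 1 and FLASH 2. The length trend was read on protein-coding genes with a mean log2 CPM over 3.

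The pipeline was tested on simulated data with 200 changed genes. It recovered 55, 66 and 62% of 2-fold and 93, 95 and 96% of 4-fold changes at the 3 group sizes, with 1.99, 4.17 and 3.07% false calls. A length trend simulated in 3 CONV libraries with no gene changed gave 9 calls without the offset and 0 with it. That simulation left the other groups without a trend. Its spread per gene came from the real libraries, which already held their own length trend. It does not measure how many calls in the data came from that trend. No pair of libraries was a duplicate (lowest chi-square per degree of freedom 30.03). Counting intervals cover counting error only. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.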

Results

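The jejunum of C57BL/6 mice, an inbred laboratory strain, was profiled by RNA sequencing 16 h after a single 15 Gy dose to the abdomen. The dose was delivered at an ultra-high rate (FLASH) or at a conventional rate (CONV), and mice that received no radiation formed the control group. The mice were 8 to 12 weeks old, and RNA came from whole jejunum, a tissue of epithelium, lamina propria, vessels and muscle. There were 6 control, 5 CONV and 7 FLASH libraries. Total estimated counts per library ranged from 24.3 to 27.8 M in controls, from 19.9 to 27.0 M in CONV and from 23.1 to 30.2 M in FLASH. The labels do not say whether each library came from its own mouse, so the p-values measure the spread between these libraries. The series title names vascular function and intestinal regeneration after FLASH, and the comparisons below ask how each dose rate changed the jejunum and where the 2 dose rates differed.

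The first principal component held 37.5% of the variance and set irradiated against control libraries (exact permutation p = 0.00649 for CONV, with overlapping libraries, and 0.000583 for FLASH, the smallest that 1716 splits can give). The second held 19.0% and separated FLASH from CONV with no overlap (exact permutation p = 0.00126, the smallest that 792 splits can give). Library composition also varied with transcript length within every group. The slope of log2 expression on transcript length was 0.11 ± 0.28 in controls (SD, n = 6), -0.18 ± 0.21 in CONV (n = 5) and 0.04 ± 0.20 in FLASH (n = 7). The most negative slopes were -0.41 in control 6, -0.43 in CONV 6 and -0.34 in FLASH 1. Control 6 and CONV 6 also had the lowest scores on the second component (-79.1 and -67.8). FLASH 7, with the highest slope in FLASH (0.27), had the highest score (82.9). FLASH 1 scored 15.4, above every CONV library, despite its slope. How much of the separation on the second component follows the length trend was not tested. FLASH and CONV differed in this slope by 0.22 (exact permutation p = 0.104). Among well-expressed protein-coding genes that passed the gene test in CONV against control, 86.8% of the shortest quintile and 21.2% of the longest quintile were higher. The shares in FLASH against CONV ran the other way, 19.3% of the shortest quintile and 83.8% of the longest, while those in FLASH against control were 61.7% and 54.2%.

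**Figure D1:**
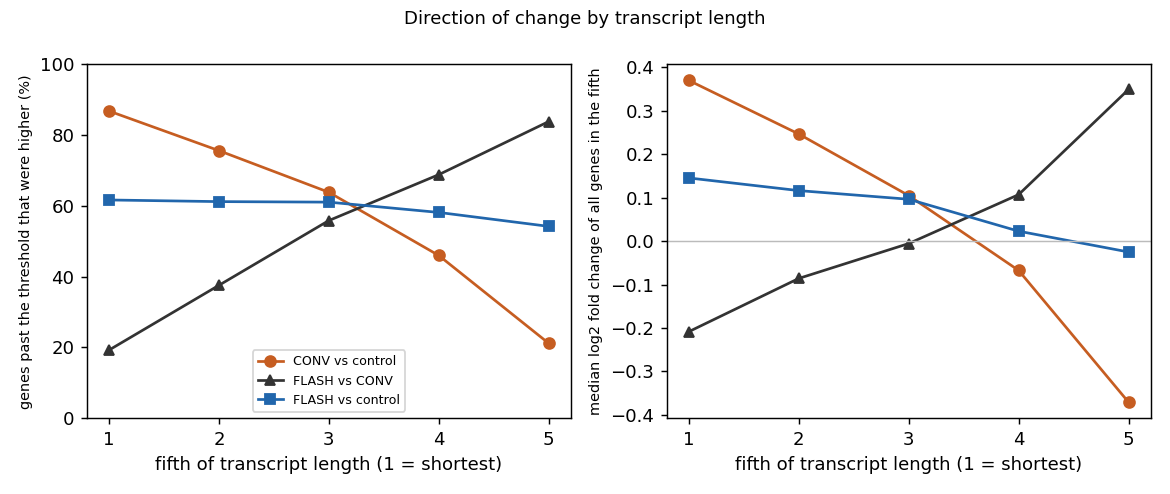
Direction of change by quintile of transcript length, for 8942 well-expressed protein-coding genes. The left panel gives the percentage of genes past the threshold that were higher and the right panel the median log2 fold change of all genes in the quintile; each line is 1 comparison, and the CONV and FLASH against CONV lines slope in opposite directions while the FLASH against control line is nearly flat, from 61.7% to 54.2%.

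CONV against control asked how the jejunum responded to 15 Gy at the conventional dose rate. Most p53 target genes rose, and so did many genes of fatty acid oxidation, absorptive enterocytes and antioxidant defence. Many genes of crypt base stem cells, mitosis, lymphocytes, plasma cells and antigen presentation fell. Of these lists only p53 targets passed camera with an estimated correlation, while the others had adjusted p from 0.275 to 0.589. Of 16257 genes tested with edgeR, 3615 passed an adjusted p of 0.05, of which 1662 were higher and 1953 lower, and 1970 of them changed more than 2-fold (677 higher, 1293 lower). Of all 16257 genes, 1691 had no CONV library overlapping a control library, where chance gives 0.433% of genes, and 1410 of the 1691 passed. The camera test called 17 of 42 gene lists, 7 higher and 10 lower. With the length and GC trend of each library removed, 4045 genes passed, 2982 of them also without that correction, and all 17 list calls held.

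Of 24 measured p53 target genes, 19 rose, 0 fell and 5 did not pass (20 rose adjusted over the list alone). The list passed camera (adjusted p = 4.2e-24), also with an estimated correlation (adjusted p = 2.1e-05) and by exact permutation of the library scores (adjusted p = 0.00909). Phlda3, a p53-induced repressor of Akt signalling on chromosome 1 (135766119 to 135769136, mm10), rose by 4.01 ± 0.18 (log2, SE; adjusted p = 6.6e-11), from 4.34 ± 1.11 CPM in controls (SD, n = 6) to 69.9 ± 10.3 CPM in CONV (n = 5). The receptor gene Eda2r rose by 4.69 ± 0.25, Ccng1 by 3.48 ± 0.21 and Psrc1 by 2.66 ± 0.15. The stress cytokine Gdf15 rose by 4.72 ± 0.36, the cyclin-dependent kinase inhibitor Cdkn1a by 1.23 ± 0.22 and Mdm2, which targets p53 for degradation, by 1.70 ± 0.18. Control 6 had the highest p53 list score among controls, a mean log2 CPM of 4.39 against 4.09 in the next.

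In the mitosis list 10 of 20 genes fell and 10 did not pass (12 fell adjusted over the list alone), among them Mki67 by -2.42 ± 0.44 and Kif23 by -1.27 ± 0.23. The list passed camera (adjusted p = 0.000781) and exact permutation (adjusted p = 0.0195), with an adjusted p = 0.589 with an estimated correlation. Of 16 crypt base stem cell genes 10 fell and 6 did not pass (11 fell adjusted over the list alone). Olfm4, a marker of crypt base columnar cells, went from 762 ± 142 to 31.2 ± 27.7 CPM (log2 fold change -4.61 ± 0.58, adjusted p = 4.0e-05), Myb fell by 1.66 ± 0.25 on the log2 scale and Lgr5 by 1.86 ± 0.41. This list passed camera (adjusted p = 2.8e-06) and exact permutation (adjusted p = 0.0165), with an adjusted p = 0.366 with an estimated correlation. Ccne2, which encodes cyclin E2, rose by 1.5045 ± 0.26. Among the largest falls were Gsdmc4 (log2 fold change -7.23 ± 0.73), Gsdmc3 (-6.96 ± 0.95) and Gsdmc2 (-6.44 ± 0.75), members of the gasdermin C cluster on chromosome 15 that may share reads. Gsdmc4 went from 152 ± 93.2 CPM in controls to 1.03 ± 0.58 CPM in CONV. Pla2g4c, a cytosolic phospholipase gene, fell by 5.61 ± 1.49 on the log2 scale (adjusted p = 0.0136) with 47.1 ± 65.7 CPM in controls, and did not pass with limma-voom (adjusted p = 0.06235), with no filter but 1 count (0.0536) or with 1 surrogate variable (0.0587). Leaving out single libraries moved Pla2g4c to -4.98 (without control 1) and -4.91 (without control 2), Gsdmc3 to -7.73 (without CONV 6) and Olfm4 to -5.33 (without CONV 7).

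Immune lists moved in different ways. Neutrophil genes rose in 3 of 8 cases, and the list passed exact permutation (adjusted p = 0.00909) but not camera (adjusted p = 0.206). Interferon-stimulated genes rose in 2 and fell in 3 of 20 cases (camera adjusted p = 0.634, exact permutation adjusted p = 0.584). Inflammatory cytokine and NF-kB genes had a camera adjusted p = 0.857 and an exact permutation adjusted p = 0.790. In the antigen presentation list 15 of 18 genes fell and 3 did not pass (15 adjusted over the list alone), including Ciita, the master regulator of MHC class II transcription, by 2.16 ± 0.37 on the log2 scale and H2-Eb1 by 1.87 ± 0.29. T and NK cell genes fell in 13 of 18 cases (17 adjusted over the list alone), with Thy1 at -1.91 ± 0.29 and Cd3e at -1.53 ± 0.28. Plasma cell genes fell in 7 of 12 cases (11 adjusted over the list alone), with Igha at -2.94 ± 0.34 and Jchain at -2.66 ± 0.44. Macrophage and dendritic cell genes fell in 9 of 16 cases (9 adjusted over the list alone), with Xcr1, a marker of cross-presenting dendritic cells, at -3.17 ± 0.41 and Flt3 at -2.64 ± 0.44. The camera adjusted p-values were 1.9e-08, 5.3e-08, 5.5e-07 and 0.000813 for these 4 lists, against adjusted p = 0.312, 0.312, 0.297 and 0.449 with an estimated correlation. Exact permutation gave adjusted p = 0.00909 for the first 3 and 0.0195 for the fourth. B cell genes fell in 6 of 10 cases (9 adjusted over the list alone), with Cd79a at -2.79 ± 0.54, and passed camera (adjusted p = 0.00442) but not exact permutation (adjusted p = 0.0950), with an adjusted p = 0.589 with an estimated correlation. Immunoglobulin genes held 1.06 to 1.97% of counts in controls and 0.111 to 0.371% in CONV, highest in CONV 7. The largest falls included the immunoglobulin variable segments Igkv8-28 (-7.78 ± 1.14), Ighv2-3 (-6.09 ± 1.11), Igkv4-63 (-4.91 ± 0.87), Igkv3-10 (-4.89 ± 0.79) and Ighv1-85 (-4.64 ± 1.11), whose reads can be shared among near-identical segments. Ighv1-85 was at -3.43 without control 4, which had 43.9 CPM against 1.39 to 13.9 in the other controls. Igkv8-28 was at -6.89 without control 6 and -8.39 without CONV 5, and Ighv2-3 at -5.22 without control 5 and -6.73 without CONV 2. Without CONV 7, Igkv4-63 was at -5.58, Igkv3-10 at -5.68 and Ighv1-85 at -5.45.

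The largest rises belonged to Psca, a GPI-anchored surface protein gene on chromosome 15 (74714839 to 74717069, mm10), at 8.35 ± 0.62 (adjusted p = 6.2e-08), and to its neighbours Gml2 (6.43 ± 0.60) and Gml (6.23 ± 0.65). Psca was near the detection limit in controls, with 14 counts over 6 libraries. Other large rises were in Sult6b2 (5.76 ± 0.97), the dopamine transporter gene Slc6a3 (5.60 ± 0.80), the cytochrome P450 genes Cyp2c29 (5.44 ± 0.79), Cyp3a44 (5.32 ± 0.38) and Cyp4a10 (4.94 ± 1.09), and the nuclear receptor gene Nr0b2 (5.11 ± 0.64). The antimicrobial gene Lcn2 rose by 4.49 ± 0.77. Single libraries moved several of these values. Sult6b2 was at 4.34 without CONV 6, which had 44.2 CPM against 1.19 to 10.1 in the other CONV libraries, and Lcn2 at 3.538 and Gml2 at 5.74 without that library. Without control 6, Cyp2c29 was at 6.90, Slc6a3 at 6.53 and Cyp4a10 at 5.73. Cyp4a10 was at 5.58 without control 4 and Psca at 8.99 without control 1. P450 genes have close paralogs, so reads may be divided among copies. In the fatty acid oxidation and PPAR list 10 of 16 genes rose, 0 fell and 6 did not pass (13 rose and 1 fell adjusted over the list alone), with Acot1 at 3.90 ± 0.48, Pdk4 at 2.39 ± 0.42 and Acadl at 2.06 ± 0.25. Absorptive enterocyte genes rose in 11 of 20 cases (11 adjusted over the list alone), with the fructose transporter gene Slc2a5 at 3.10 ± 0.48, Apoa4 at 2.21 ± 0.39 and Fabp2 at 1.74 ± 0.30. NRF2 antioxidant genes rose in 8 of 16 cases (10 adjusted over the list alone), with Gsta4 at 2.39 ± 0.40 and Hmox1 at 1.99 ± 0.31. These 3 lists had camera adjusted p = 5.0e-07, 4.6e-05 and 2.7e-05, exact permutation adjusted p = 0.00909 each, and adjusted p = 0.312, 0.404 and 0.275 with an estimated correlation.

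Circadian clock genes rose in 8 of 15 cases and fell in 1 (8 and 2 adjusted over the list alone), with Per3 at 1.93 ± 0.33 and Tef at 1.83 ± 0.25 (camera adjusted p = 0.0126, exact permutation adjusted p = 0.00909, adjusted p = 0.368 with an estimated correlation). Unfolded protein response genes rose in 5 of 14 cases (8 rose and 1 fell adjusted over the list alone), with Creld2 at 1.14 ± 0.26 (camera adjusted p = 0.00884, exact permutation adjusted p = 0.0195, adjusted p = 0.312 with an estimated correlation). Sterol synthesis genes rose in 7 of 18 cases (9 adjusted over the list alone), with Insig1 at 1.58 ± 0.38. That list passed camera (adjusted p = 0.0126) but not exact permutation (adjusted p = 0.156) and had an adjusted p = 0.620 with an estimated correlation. Its camera call was lost without control 6 (adjusted p = 0.0830), without CONV 5 (adjusted p = 0.0634) or without the steepest-length libraries control 6, CONV 6 and FLASH 1 (adjusted p = 0.153), and fry gave an adjusted p = 0.148.

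Smooth muscle genes fell in 6 of 14 cases (10 adjusted over the list alone), with Acta2 at -1.43 ± 0.40. Fibroblast and matrix genes fell in 6 of 16 cases (7 adjusted over the list alone), with Col6a3 at -2.34 ± 0.57 and Col3a1 at -1.75 ± 0.41. Camera gave adjusted p = 0.000631 and 0.00119, exact permutation adjusted p = 0.0657 and 0.0766, and the estimated correlation adjusted p = 0.589 for both. Pericyte genes fell in 1 of 9 cases (camera adjusted p = 0.149, exact permutation adjusted p = 0.179), and neuron and glia genes had a camera adjusted p = 0.167 and an exact permutation adjusted p = 0.302. CONV 6 had the lowest smooth muscle score, a mean log2 CPM of 3.06 against 5.18 in the next CONV library. The Wnt, R-spondin and BMP niche list had 4 of 15 genes lower (4 adjusted over the list alone), with Wnt2b at -1.55 ± 0.41. It passed camera (adjusted p = 0.0126), not exact permutation (adjusted p = 0.119), with an adjusted p = 0.589 with an estimated correlation and a camera adjusted p = 0.122 without CONV 6 and 0.0633 without the steepest-length libraries, and fry gave an adjusted p = 0.0814. The other 15 lists that camera called in this comparison also passed fry. Of 20 endothelial cell genes, 2 fell and 18 did not pass (0 adjusted over the list alone), and camera gave an adjusted p of 0.265. Pecam1, Kdr and Plvap had log2 fold changes of -0.82 ± 0.39, -1.14 ± 0.53 and -0.87 ± 0.37 (adjusted p = 0.126, 0.119 and 0.0958). Without control 6 these 3 passed, with adjusted p = 0.0409, 0.02205 and 0.0217. Vwf, the von Willebrand factor gene, fell by 2.30 ± 0.69 on the log2 scale (adjusted p = 0.0240), and by 1.44 without control 2 (adjusted p = 0.0902). Without CONV 2, CONV 6 or CONV 7 its log2 fold change was -2.21, -2.13 and -2.16, but it no longer passed (adjusted p = 0.0611, 0.0711 and 0.0540). It also did not pass with no filter but 1 count (-2.25, adjusted p = 0.0755), limma-voom (-1.64, 0.117), limma-trend (-1.63, 0.0702), replicate number as a block (-2.02, 0.129) or 1 surrogate variable (-1.004, 0.0669). Clu, a marker of regenerating epithelium, had a log2 fold change of -0.09 ± 0.71 (adjusted p = 0.932), and 1.32 without control 2 (adjusted p = 0.0915).

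The count of 3615 genes moved to 6493 without control 6 and to 1869, 2171, 2277 and 2359 without CONV 6, CONV 2, control 2 and control 5. Library totals in place of TMM factors lowered the share of higher calls from 46.0 to 24.2% and the median log2 fold change of all genes from -0.04 to -0.25. In 27 of 60 splits of the same libraries, the real one included, camera called at least 17 lists, so the number of lists called does not set the groups apart, and only p53 targets kept their camera call with an estimated correlation.

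FLASH against control asked how the jejunum responded to the same dose at the ultra-high rate. Most p53 target genes rose, and so did many genes of fatty acid oxidation, enterocytes and antioxidant defence. Many genes of crypt base stem cells, mitosis, lymphocytes, antigen presentation, Paneth cells, DNA replication, the stem cell niche and smooth muscle fell. Of these lists only p53 targets passed camera with an estimated correlation, while the others had adjusted p from 0.236 to 0.444. edgeR called 6135 of 16257 genes, 2719 higher and 3416 lower, with 3198 changed more than 2-fold (1219 higher, 1979 lower). The groups did not overlap in 2243 of all 16257 genes, where chance gives 0.117% of genes, and 2233 of the 2243 passed. Camera called 23 of 42 lists, 9 higher and 14 lower, of which all 23 also passed exact permutation of the library scores and fry, and 1 passed with an estimated correlation. With the length and GC trend removed, 7355 genes passed, 5955 of them also without that correction, and 21 of the 23 lists held.

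Of 24 p53 target genes 21 rose, 1 fell and 2 did not pass (21 and 1 adjusted over the list alone). The list passed camera (adjusted p = 6.4e-17), also with an estimated correlation (adjusted p = 0.000179). Phlda3 rose by 3.14 ± 0.17 (adjusted p = 8.2e-10), to 38.2 ± 4.42 CPM (SD, n = 7), and Eda2r by 3.77 ± 0.24. Sesn2 rose by 2.09 ± 0.17, the nuclease gene Aen by 1.60 ± 0.13, Cdkn1a by 1.81 ± 0.21 and Mdm2 by 1.40 ± 0.17. In the mitosis list 14 of 20 genes fell (15 adjusted over the list alone), with Mki67 at -1.84 ± 0.38 and Ccna2 at -0.90 ± 0.14. DNA replication genes fell in 13 of 20 cases and rose in 1 (14 and 1 adjusted over the list alone), with Lig1 at -2.11 ± 0.22 and Mcm5 at -1.40 ± 0.19. The gene that rose was Rrm2, a subunit of ribonucleotide reductase, at 3.35 ± 0.33, from 21.2 ± 2.14 to 216 ± 92.8 CPM. DNA repair genes fell in 11 of 20 cases and rose in 1 (11 and 1 adjusted over the list alone). Exo1 fell by 1.29 ± 0.23 on the log2 scale and Ercc5, of nucleotide excision repair, rose by 1.09 ± 0.16. Camera adjusted p-values of these 3 lists were 1.8e-05, 9.5e-05 and 0.00945, exact permutation gave adjusted p = 0.00459, 0.00204 and 0.0117, and the estimated correlation gave adjusted p = 0.402, 0.255 and 0.444.

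Of 16 crypt base stem cell genes 12 fell and 4 did not pass (14 fell adjusted over the list alone), with Olfm4 at -3.94 ± 0.49, Myb at -2.40 ± 0.23, Cdca7 at -1.53 ± 0.15 and Lgr5 at -2.10 ± 0.37. Of 14 Paneth cell genes 12 fell and 2 did not pass (12 adjusted over the list alone). The lysozyme gene Lyz1 fell by 1.60 ± 0.22 on the log2 scale, from 6721 ± 957 to 2210 ± 814 CPM, Mptx2 by 2.46 ± 0.32 and Defa26 by 1.97 ± 0.24, where defensin copies may share reads. The Wnt, R-spondin and BMP niche list had 13 of 15 genes lower and 1 higher (13 and 1 adjusted over the list alone), with the BMP antagonist gene Grem1 at -2.42 ± 0.52 and Sfrp1 at -1.28 ± 0.23. Camera adjusted p-values were 5.5e-06, 1.7e-07 and 0.000679 for stem cell, Paneth cell and niche lists, exact permutation gave adjusted p = 0.00204 for each, and the estimated correlation gave adjusted p = 0.316, 0.243 and 0.412. Fetal-like epithelium genes rose in 6 of 13 cases and fell in 1 (6 and 1 adjusted over the list alone), with Anxa8 at 2.92 ± 0.42 and Ly6a at 1.84 ± 0.33. That list had a camera adjusted p = 0.0193 that became 0.0509 with the length and GC trend removed, and an adjusted p = 0.412 with an estimated correlation. Clu had a log2 fold change of -0.10 ± 0.65 (adjusted p = 0.922), and rose by 1.37 without control 2 (adjusted p = 0.0402).

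In the fatty acid oxidation and PPAR list 14 of 16 genes rose and 2 did not pass (14 adjusted over the list alone). Pdk4, a kinase that restrains glucose oxidation and lies on chromosome 6 (5483351 to 5496309, mm10), rose by 6.51 ± 0.49 (adjusted p = 5.5e-08), from 5.55 ± 2.49 to 504 ± 219 CPM, Acot1 by 4.24 ± 0.48 and Acadl by 2.5999 ± 0.24. Absorptive enterocyte genes rose in 15 of 20 cases (16 adjusted over the list alone), with Slc2a5 at 3.46 ± 0.47, Slc2a2 at 2.47 ± 0.34 and Mttp at 1.79 ± 0.18. NRF2 antioxidant genes rose in 9 of 16 cases (9 adjusted over the list alone), with Gclc at 2.58 ± 0.31 and Hmox1 at 2.31 ± 0.29. Circadian clock genes rose in 10 of 15 cases (11 rose and 2 fell adjusted over the list alone), with Ciart at 4.01 ± 0.47 and Tef at 2.57 ± 0.24. Libraries of both irradiated groups differed in clock phase genes. The log2 CPM of Dbp minus Arntl was a measure chosen after seeing the data. It was -2.46 in FLASH 1 and -2.17 in FLASH 2, within the controls (-3.47 to -0.14), and 0.45 to 2.15 in the other FLASH libraries. In CONV 7 (-1.46) and CONV 3 (-0.60) it also lay within the controls, and in CONV 6 it reached 2.74. It was higher than in controls by 2.70 in FLASH (exact permutation p = 0.0146) and by 3.13 in CONV (exact permutation p = 0.0108), and the labels give no time of collection. For the fatty acid oxidation, enterocyte, NRF2 and clock lists camera adjusted p-values were 2.3e-09, 1.7e-08, 7.3e-05 and 2.8e-05, exact permutation gave adjusted p = 0.00204 each, and the estimated correlation gave adjusted p = 0.236, 0.236, 0.236 and 0.177. Hypoxia genes rose in 7 of 17 cases and fell in 1 (7 and 1 adjusted over the list alone), with Ndrg1 at 2.98 ± 0.29 and Vegfa at 1.23 ± 0.16 (camera adjusted p = 0.0227, adjusted p = 0.316 with an estimated correlation). Mitochondrially encoded genes rose in 4 of 13 cases (3 adjusted over the list alone), with mt-Nd1 at 0.79 ± 0.19, which did not pass with library totals (adjusted p = 0.0912) or with replicate number as a block (0.0524), and both that gene (adjusted p = 0.298) and the list (camera adjusted p = 0.00494, 0.150 after correction) did not pass with the length and GC trend removed. The list had an adjusted p = 0.412 with an estimated correlation, and reads of mitochondrial genes can also match nuclear copies.

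Neutrophil marker Ly6g had 3332 counts over the FLASH libraries and 1 over the controls, and the 1 count was in control 3. This gave a ratio of 3515 with a 95% counting interval of 630.5 to 138900, which leaves out the spread between libraries. Ly6g ranged from 0.567 to 42.7 CPM in FLASH and from 0.319 to 9.21 CPM in CONV, against at most 0.0365 CPM in controls. Psca (9.17 ± 0.63), Gml (7.25 ± 0.66), Gml2 (7.03 ± 0.60), Sult6b2 (7.93 ± 1.01), Cyp2c29 (7.20 ± 0.82), Slc6a3 (6.32 ± 0.79) and Cyp2d10 (6.20 ± 0.48) made up most of the other large rises. Psca was at 9.85 without control 1, and Cyp2c29 at 8.65 and Slc6a3 at 7.25 without control 6. In the epithelial antimicrobial list 9 of 13 genes rose and 2 fell (9 and 2 adjusted over the list alone), with Lcn2 at 5.97 ± 0.81 and Saa3 at 4.07 ± 0.58 (camera adjusted p = 0.0193, adjusted p = 0.412 with an estimated correlation). The hypoxia, antimicrobial and fetal-like lists passed exact permutation (adjusted p = 0.00350, 0.0163 and 0.0117) and lost their camera call without FLASH 1 and FLASH 2, left out after seeing the data (adjusted p = 0.0597, 0.0801 and 0.0798), and without the steepest-length libraries (adjusted p = 0.0509, 0.0915 and 0.0578).

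Immune lists moved in different ways. Neutrophil genes rose in 5 of 8 cases and fell in 1, and inflammatory cytokine and NF-kB genes rose in 1 of 15 and fell in 4. Both passed exact permutation (adjusted p = 0.00459 and 0.0254) but not camera (adjusted p = 0.0738 and 0.227). Antigen presentation genes fell in 15 of 18 cases (17 adjusted over the list alone), with Gbp6 at -3.26 ± 0.36 and Ciita at -2.92 ± 0.34. Interferon-stimulated genes fell in 10 of 20 cases and rose in 1 (10 and 1 adjusted over the list alone), with the chemokine gene Cxcl10 at -3.24 ± 0.45. T and NK cell genes fell in 12 of 18 cases (13 adjusted over the list alone), with Thy1 at -1.96 ± 0.26, and plasma cell genes in 9 of 12 (11 fell and 1 rose adjusted over the list alone), with Tnfrsf17 at -3.68 ± 0.46 and Igha at -2.42 ± 0.29. B cell genes fell in 9 of 10 cases (9 adjusted over the list alone), with Cd79a at -3.65 ± 0.50. Macrophage and dendritic cell genes fell in 10 of 16 cases and rose in 2 (10 and 2 adjusted over the list alone), with Clec9a at -3.42 ± 0.45 and Xcr1 at -2.60 ± 0.35. Camera adjusted p-values for these 6 lists were 9.9e-07, 0.0105, 0.000587, 5.5e-06, 0.000330 and 0.0226, exact permutation gave adjusted p = 0.00204, 0.0117, 0.00350, 0.00204, 0.00204 and 0.00515, and the estimated correlation gave adjusted p = 0.274, 0.542, 0.412, 0.236, 0.412 and 0.447. The macrophage and dendritic cell list did not pass camera without control 2 (adjusted p = 0.05825). The largest fall outside immunoglobulin segments was in Apol10a, an apolipoprotein L family gene on chromosome 15 (77477047 to 77491069, mm10), from 519 ± 154 to 7.98 ± 4.68 CPM (log2 fold change -6.02 ± 0.58, adjusted p = 7.4e-07). Igkv8-28 fell by 7.50 ± 0.96 on the log2 scale, and Igkv2-112, Ighv5-9, Igkv3-5, Igkv3-10, Igkj5, Igkv4-70 and Igkv8-19 had log2 fold changes from -5.25 to -3.66. Without control 4, at 64.3 CPM against 1.31 to 3.50 in the other controls, Ighv5-9 was at -1.75. Igkv8-28 was at -6.61 without control 6 and -8.24 without FLASH 2, and Igkv2-112 at -5.90 without FLASH 1. Immunoglobulin genes held 0.126 to 0.341% of counts in FLASH.

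All 14 smooth muscle genes fell (14 adjusted over the list alone), with Mylk at -1.65 ± 0.27 and Smtn at -1.52 ± 0.33, and fibroblast and matrix genes fell in 10 of 16 cases and rose in 1 (12 and 1 adjusted over the list alone), with Col6a3 at -3.33 ± 0.52 and Col3a1 at -2.06 ± 0.37. Both passed camera (adjusted p = 0.000330 and 0.00317) and exact permutation (adjusted p = 0.00515 each), with adjusted p = 0.444 and 0.447 with an estimated correlation. Pericyte genes fell in 3 of 9 cases (camera adjusted p = 0.0669, exact permutation adjusted p = 0.0176), and neuron and glia genes rose in 1 of 14 and fell in 2 (camera adjusted p = 0.235, exact permutation adjusted p = 0.127). Among 20 endothelial cell genes 1 rose, 1 fell and 18 did not pass (0 adjusted over the list alone, camera adjusted p = 0.474), and the median log2 fold change was -0.21. Camera ranked the list as higher while its median was negative; without control 2 it passed as higher (adjusted p = 0.0189), and without control 6 it pointed lower (adjusted p = 0.863). Pecam1, Kdr and Plvap had log2 fold changes of -0.29 ± 0.35, -0.56 ± 0.47 and -0.18 ± 0.34 (adjusted p = 0.547, 0.371 and 0.711), which became 0.34, 0.15 and 0.44 without control 2 (adjusted p = 0.286, 0.812 and 0.138). Vwf was at -1.08 ± 0.59 (adjusted p = 0.154) and passed without control 6 (log2 fold change -1.33, adjusted p = 0.0441).

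Library totals in place of TMM factors lowered the share of higher calls in FLASH against control from 44.3 to 17.4% and the median log2 fold change of all genes from -0.07 to -0.44. In 8 of 60 splits of these libraries, the real one included, camera called at least 23 lists.

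**Figure D2:**
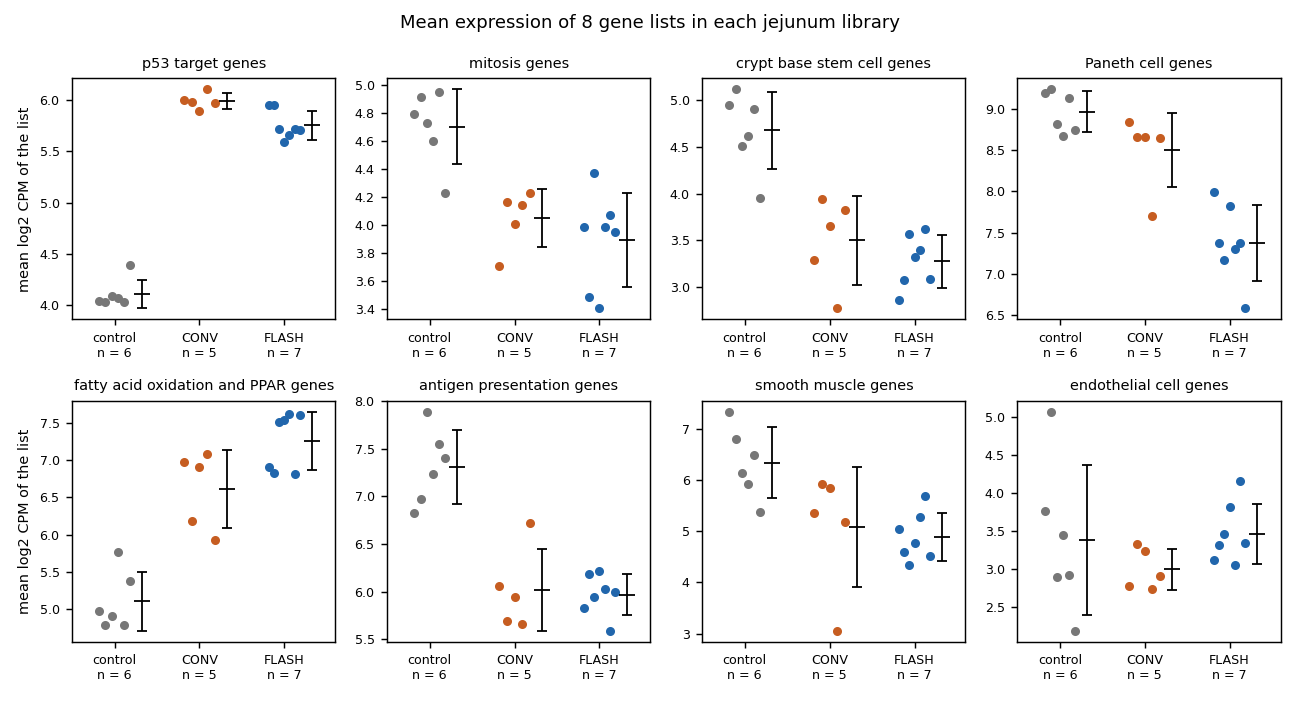
Mean log2 CPM of the measured members of 8 gene lists in each library. Points are libraries (6 control, 5 CONV, 7 FLASH) and bars are group means with SD; p53 target scores lay between 5.59 and 6.10 in irradiated and between 4.03 and 4.39 in control libraries, while endothelial scores of the 3 groups overlapped.

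FLASH against CONV compared the dose rates directly. FLASH jejunum had higher expression of Zbtb16, Fkbp5, Sgk1, Pdk4 and Pck1, and lower expression of 11 of 14 Paneth cell genes, 7 of 24 p53 targets and 7 of 14 unfolded protein response genes. edgeR called 3217 of 16257 genes, 1606 higher and 1611 lower in FLASH, and 1347 of them differed more than 2-fold (732 higher, 615 lower). No FLASH library overlapped a CONV library in 1386 of all 16257 genes, where chance gives 0.253% of genes, and 1313 of the 1386 passed. Camera called 11 of 42 lists, 6 higher and 5 lower. With an estimated correlation the adjusted p of these 11 lists ran from 0.524 to 0.962. Their exact permutation p ran from 0.00126, the smallest that 792 splits can give, to 0.0354, and after adjustment from 0.0530 to 0.114. A single list at the smallest p adjusts to 0.0530 over 42 lists, so the adjusted exact test could not call 1 list by itself. Several lists at that p together could have passed, and the test called none of the 11.

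The largest rise was in Zbtb16, which encodes the transcription factor PLZF on chromosome 9 (48654297 to 48836222, mm10), at 5.11 ± 0.63 (log2, SE; adjusted p = 0.000151), from 1.11 ± 0.62 CPM in CONV (SD, n = 5) to 37.9 ± 19.8 CPM in FLASH (n = 7). Pdk4 followed at 4.12 ± 0.47 (29.1 ± 13.7 to 504 ± 219 CPM), Pck1, the gluconeogenic enzyme gene, at 4.05 ± 0.40 (107 ± 45.2 to 1769 ± 712 CPM) and the serum and glucocorticoid kinase gene Sgk1 at 3.56 ± 0.47 (125 ± 31.2 to 1477 ± 771 CPM). Fkbp5, a glucocorticoid receptor co-chaperone gene on chromosome 17 (28399094 to 28517527, mm10), rose by 3.403 ± 0.41 (36.6 ± 16.8 to 387 ± 141 CPM). The metallothionein gene Mt2 rose by 3.41 ± 0.76, the lipoprotein lipase inhibitor gene Angptl4 by 3.05 ± 0.45, Cemip, of hyaluronan breakdown, by 3.55 ± 0.42, and Plat, which encodes tissue plasminogen activator, by 3.14 ± 0.48. Akp3, an intestinal alkaline phosphatase gene, rose by 4.002 ± 0.92 with a wide spread (16.1 ± 30.04 CPM in FLASH) and did not pass with limma-voom (adjusted p = 0.0527). Without FLASH 9, at 83.8 CPM against 2.13 to 12.0 in the other FLASH libraries, its log2 fold change was 2.27. Every FLASH library lay above every CONV library for these 10 genes, which was a condition for naming them.

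**Figure D3:**
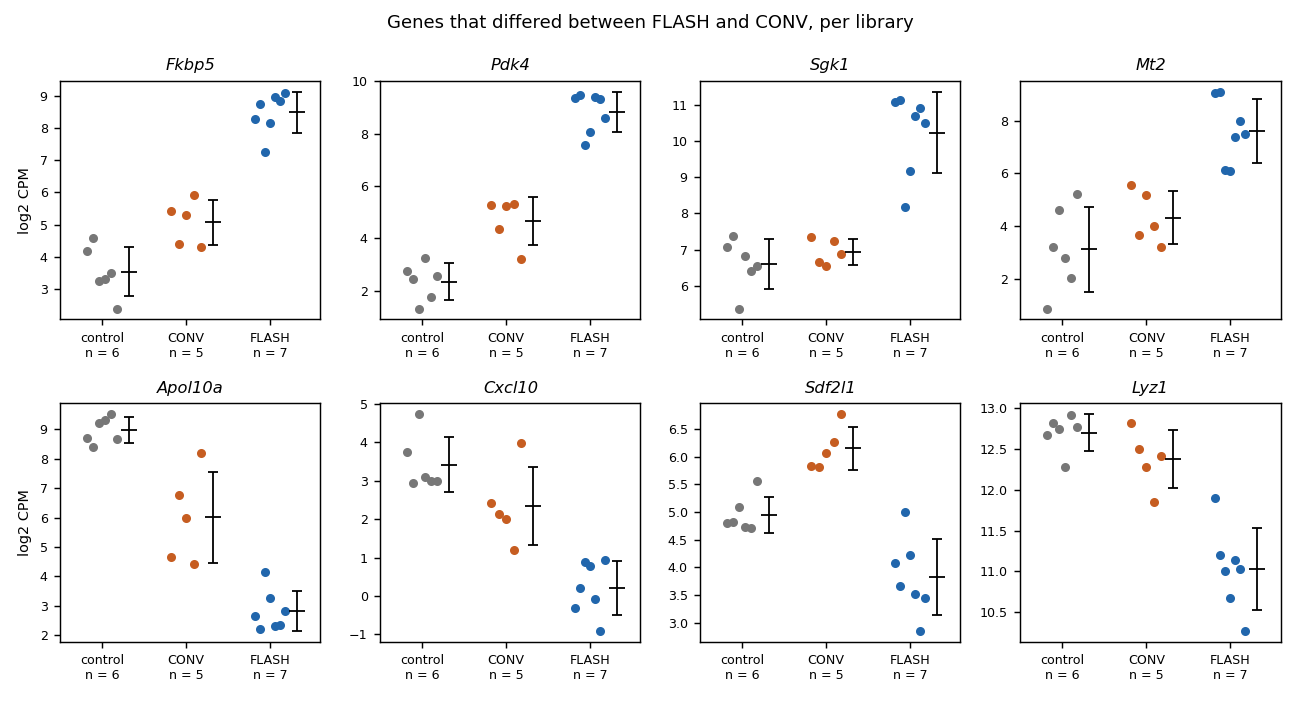
Expression of 8 genes in each library, in log2 CPM. Points are libraries (6 control, 5 CONV, 7 FLASH) and bars are group means with SD; Fkbp5, Pdk4, Sgk1 and Mt2 were higher in every FLASH than in every CONV library, Apol10a, Cxcl10 and Sdf2l1 were lower in every FLASH library, and the Lyz1 groups overlapped.

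Among the largest falls, Apol10a differed by -3.68 ± 0.53 (adjusted p = 0.000349), from 102 ± 112 CPM in CONV to 7.98 ± 4.68 CPM in FLASH, against 519 ± 154 CPM in controls. It was at -2.78 without CONV 7, which had 291 CPM against 21.6 to 109 in the other CONV libraries. The interferon-inducible genes Cxcl10 (-2.32 ± 0.45), Apol7c (-2.03 ± 0.41), Batf2 (-1.84 ± 0.37) and Ifi27l2a (-1.79 ± 0.37) were lower in FLASH, with Cxcl10 at -1.66 without CONV 7. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, was at -2.22 ± 0.29, the collagen chaperone gene Serpinh1 at -1.90 ± 0.33 and the Hsp90 co-chaperone gene Chordc1 at -2.00 ± 0.34. Ccne2 differed by -1.82 ± 0.25 and Pagr1a by -2.15 ± 0.47. Of 20 interferon-stimulated genes 4 were lower and 16 did not pass (4 adjusted over the list alone), with Mx2 at -1.29 ± 0.31. The camera call of that list (adjusted p = 0.0104, 0.962 with an estimated correlation, exact permutation adjusted p = 0.114, fry adjusted p = 0.123) was lost without CONV 7 (adjusted p = 0.0539), whose score of 4.98 was the highest against 3.87 in the next.

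Paneth cell genes were lower in 11 of 14 cases and 3 did not pass (12 adjusted over the list alone). Mmp7, the protease that activates defensins, was at -1.42 ± 0.19, Lyz1 at -1.30 ± 0.23, Mptx2 at -1.59 ± 0.32 and Defa17 at -1.29 ± 0.24. Camera gave an adjusted p = 5.7e-07, exact permutation an adjusted p = 0.0589 and the estimated correlation an adjusted p = 0.524. Mean log2 CPM over the list was 8.97 ± 0.25 in controls, 8.50 ± 0.45 in CONV and 7.37 ± 0.46 in FLASH. CONV 6 had the lowest score among CONV libraries, 7.70 against 8.65 in the next. Mitochondrially encoded genes were higher in 7 of 13 cases (9 adjusted over the list alone), with mt-Nd1 at 1.10 ± 0.21 and mt-Atp8 at 0.98 ± 0.20 (camera adjusted p = 0.000929, exact permutation adjusted p = 0.0530, adjusted p = 0.524 with an estimated correlation), and their reads can also match nuclear copies.

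p53 target genes were split between the dose rates. In FLASH 7 of 24 were lower, 2 were higher and 15 did not pass (10 and 3 adjusted over the list alone). Ccng1 was at -1.29 ± 0.19, Psrc1 at -1.02 ± 0.14 and Phlda3 at -0.87 ± 0.16, while Pmaip1, which encodes the death-promoting protein Noxa, was at 2.07 ± 0.47. Cdkn1a was at 0.59 ± 0.21 (adjusted p = 0.0575) and passed without FLASH 4 (adjusted p = 0.0216), without FLASH 5 (adjusted p = 0.0364), with the length and GC trend removed (adjusted p = 0.0125), with DESeq2 (adjusted p = 0.0291) and with 1 surrogate variable (adjusted p = 0.0112), and Mdm2 was at -0.30 ± 0.17 (adjusted p = 0.225). The list had a camera adjusted p = 0.0257, which was 0.0558 without FLASH 5, an exact permutation adjusted p = 0.0589 and an adjusted p = 0.524 with an estimated correlation. DNA replication genes were lower in 8 of 20 cases and higher in 1 (9 and 1 adjusted over the list alone), the higher one being Rrm2 at 2.53 ± 0.34 (camera adjusted p = 0.0104, exact permutation adjusted p = 0.0589, adjusted p = 0.602 with an estimated correlation). Unfolded protein response genes were lower in 7 of 14 cases and higher in 1 (7 and 2 adjusted over the list alone). Creld2 was at -1.77 ± 0.25 and Herpud1, of endoplasmic reticulum protein degradation, at 1.29 ± 0.26. That list had a camera adjusted p = 0.0257, which was 0.106 with the length and GC trend removed and 0.0545 without CONV 6, an exact permutation adjusted p = 0.0530 and an adjusted p = 0.524 with an estimated correlation.

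Fatty acid oxidation and PPAR genes were higher in 5 of 16 cases (5 higher and 1 lower adjusted over the list alone), with Cpt1a, the gatekeeper of mitochondrial fatty acid import, at 1.69 ± 0.29 and Cd36 at 1.17 ± 0.24. Absorptive enterocyte genes were higher in 5 of 20 cases and lower in 1 (7 and 1 adjusted over the list alone), with Mgam at 1.18 ± 0.28 and Mttp at 0.89 ± 0.18. Circadian clock genes were higher in 7 of 15 cases (7 adjusted over the list alone), with Per1 at 2.47 ± 0.45 and Cry2 at 1.69 ± 0.29. Hypoxia genes were higher in 6 of 17 cases (8 higher and 1 lower adjusted over the list alone), with Ndrg1 at 2.33 ± 0.31 and Slc2a1 at 1.05 ± 0.28, and YAP target genes in 3 of 11 (5 adjusted over the list alone), with Ccn2 at 1.85 ± 0.29. Camera adjusted p-values for these 5 lists were 0.0114, 0.0114, 0.0152, 0.0257 and 0.0152, exact permutation gave adjusted p = 0.114, 0.114, 0.0589, 0.0589 and 0.0589, and the estimated correlation gave adjusted p = 0.924, 0.924, 0.524, 0.524 and 0.723. Fry did not call the first 2 lists (adjusted p = 0.0568 and 0.0960). The clock list had a camera adjusted p = 0.116 with the length and GC trend removed. Without the steepest-length libraries the YAP, hypoxia and unfolded protein response lists did not pass camera (adjusted p = 0.0663, 0.0607 and 0.0705). The hypoxia list did not pass camera without CONV 3 (adjusted p = 0.0526), CONV 5 (0.0609) or FLASH 1 (0.0611), or without FLASH 1 and FLASH 2 (0.116).

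Robo4, a receptor of vascular stability, was the only 1 of 20 endothelial cell genes that passed, at 1.40 ± 0.43 (adjusted p = 0.0294), and 19 did not pass (0 adjusted over the list alone). It did not pass without CONV 2 (adjusted p = 0.0702), CONV 3 (0.0561), CONV 6 (0.0663), CONV 7 (0.0637) or FLASH 7 (0.0674). The list had a median log2 fold change of 0.54 and a camera adjusted p = 0.0588, which was 0.0474 without CONV 3 and 0.0230 without FLASH 6. Pecam1, Kdr, Plvap and Vwf were at 0.53 ± 0.37, 0.58 ± 0.51, 0.69 ± 0.36 and 1.21 ± 0.65 (adjusted p = 0.335, 0.448, 0.184 and 0.194). Plvap passed when only the 2 groups were fitted (log2 fold change 0.71, adjusted p = 0.0167) and Vwf with 1 surrogate variable (1.02, adjusted p = 0.0292). In the endothelial activation and injury list 5 of 17 genes were higher and 12 did not pass (5 adjusted over the list alone, camera adjusted p = 0.161), with Apln at 1.69 ± 0.29 and Edn1, which encodes endothelin 1, at 1.499 ± 0.37. Outside the vessels, the prohormone convertase gene Pcsk1, of enteroendocrine cells, was at 1.42 ± 0.23. None of the marker genes named in every comparison passed in the main test. Those not given above were Mki67 at 0.58 ± 0.40 (adjusted p = 0.324), Lgr5 at -0.24 ± 0.38 (0.701), Olfm4 at 0.66 ± 0.48 (0.348) and Clu at -0.00 ± 0.69 (0.998). Olfm4 passed without CONV 7 (log2 fold change 1.38, adjusted p = 0.0458). Mitosis genes were lower in 3 of 20 cases (camera adjusted p = 0.242), and crypt base stem cell genes were lower in 5 of 16 and higher in 1 (camera adjusted p = 0.513).

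With the length and GC trend of each library removed, 4004 genes passed between FLASH and CONV, 2685 of them also without that correction, and 9 of the 11 camera calls held. Library totals in place of TMM factors lowered the share of higher calls from 49.9 to 24.4% and the median log2 fold change of all genes from -0.02 to -0.18. With library totals Robo4 did not pass (adjusted p = 0.0618) and Mdm2 did (log2 fold change -0.45, adjusted p = 0.0313). With replicate number as a block, Robo4, Edn1, Mx2 and Pmaip1 did not pass (adjusted p = 0.102, 0.0591, 0.0562 and 0.0601), and neither did the p53, fatty acid oxidation and unfolded protein response lists with camera (adjusted p = 0.0510, 0.0915 and 0.0576). In 28 of 60 splits of these libraries, the real one included, camera called at least 11 lists.

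The size of the response was compared with a score per irradiated library. It was built from 942 genes risen and 1554 fallen in all irradiated libraries pooled against controls. The pool held 7 FLASH and 5 CONV libraries. Genes changed only in FLASH could thus enter the score more easily than genes changed only in CONV. A higher score in FLASH therefore does not by itself mean a larger response. The mean score was 1.81 ± 0.14 in FLASH (SD, n = 7) and 1.43 ± 0.42 in CONV (n = 5), a difference of 0.38 (two-sided exact permutation p = 0.0518). For risen genes alone the means were 1.96 ± 0.16 and 1.34 ± 0.36, a difference of 0.62 (exact permutation p = 0.00379), and for fallen genes -1.66 ± 0.16 and -1.53 ± 0.48, a difference of -0.14 (exact permutation p = 0.508). The score difference passed the threshold without CONV 6 (0.58, exact permutation p = 0.00303) or without CONV 2 (exact permutation p = 0.0303).

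The responses to the 2 dose rates were correlated across 16257 genes, with Pearson r = 0.727 and a covariance of 0.582. Genes are not independent replicates, and both comparisons used the same controls. Groups simulated without any change against those controls gave r = 0.491 and a covariance of 0.0592. With the controls split 3 and 3, r was 0.619 and the covariance 0.522, against 0.0031 and 6e-04 in the simulation. The simulation drew genes independently and held no trend across genes, such as that with transcript length. It shows the effect of shared controls only. Slopes on length were lower than in controls by -0.287 in CONV and -0.072 in FLASH, and such a common shift could also correlate the responses. Both comparisons called 1053 genes higher and 1283 lower, and the number that unchanged groups with shared controls would give was not computed. The p53 targets Phlda3 and Eda2r rose in both, while Olfm4, Lgr5 and Mki67 fell in both. Only 11 genes called higher in CONV were called lower in FLASH and 12 the reverse. Of the genes called in the same direction against control, 206 of the higher and 119 of the lower also differed between FLASH and CONV.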

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

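Of the tests below, those of length and GC bias, of dose rate as the source of the length trend, and of reads shared between defensin copies were chosen only after the result was seen.

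Single libraries stood far from the rest of their group, with a gap to the nearest library that was large against the group's range. Chance flags about 1 in 20 groups. Among library measures 2 of 14 groups had such a library, among list scores 9 of 126 and among named genes 23 of 414, where 1 in 20 would be 0.7, 6.3 and 20.7. CONV 2 had a depth of 19.936 M counts (nearest 25.909), and CONV 7 had an immunoglobulin share of 0.371% (nearest 0.177).

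In list scores, given as mean log2 CPM, control 6 stood at 4.3914 for p53 targets (nearest 4.0946), 2.9109 for YAP targets (3.5865) and 2.4592 for mesothelial genes (1.813). CONV 6 stood at 4.1346 for immediate early and heat shock genes (4.4946), 7.7039 for Paneth cell genes (8.6457) and 3.056 for smooth muscle genes (5.1839). CONV 7 stood at 4.9813 for interferon-stimulated genes (3.871) and 4.7969 for plasma cell genes (3.9564), and FLASH 7 at 3.0602 for pericyte genes (2.395).

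In log2 CPM of single genes, control 6 stood apart for Ccng1 (7.0234), Kif23 (3.5186), Lig1 (4.1546), Herpud1 (6.6994) and Dusp1 (2.4533). Control 4 did so for Ighv5-9 (6.0088) and Akp3 (0.4247), control 2 for Cd79a (6.0264) and control 3 for Ly6g (-3.1512), where the other controls had 0 counts. CONV 7 did so for Xcr1 (-0.9953), Pck1 (5.1415), Apol7c (5.7603) and Mx2 (3.4917), and CONV 6 for Acta2 (5.336), Ciart (1.1361) and Akp3 (-1.7286). CONV 3 stood apart for Cyp2c29 (2.2156) and CONV 2 for Clec9a (-2.4679). FLASH 4 did so for Gsdmc4 (0.4827), Gsdmc2 (0.3394) and Zbtb16 (2.4577), and FLASH 7 for Sult6b2 (2.0928) and Cyp2d10 (1.1647).

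Paneth cell genes were lower in FLASH than in CONV. Reads shared between defensin copies are argued against as the whole source, since the 8 members that are not defensins had a median log2 fold change of -1.1365 and 5 of them passed. Length and GC bias is argued against as the whole source, since 9 of 14 members passed with that trend removed and the list was called by camera (adjusted p = 0.002535). The median log2 fold change went from -1.1972 to -0.8332, so the trend can account for part. With an estimated correlation camera did not call the list before (adjusted p = 0.5241) or after the correction (0.8855). With a distal minus proximal score in the model 95.842% of the difference was left (permutation p = 0.005051). That score did not differ clearly between FLASH and CONV (exact permutation p = 0.674). Position along the intestine is argued against only as far as the score marks it. Fewer Paneth cells after FLASH and lower expression per cell both stay open as hypotheses, since whole tissue was measured and neither was tested.

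Among genes that passed between FLASH and CONV, those with long transcripts were mostly higher and those with short transcripts mostly lower. Without control 6, CONV 6 and FLASH 1 the gap between the longest and the shortest quintile was 69.388 percentage points, against 64.576 with all libraries. This does not decide whether a few steep libraries carried the trend. It took a library with a negative slope from both FLASH (-0.337) and CONV (-0.432), while CONV 2 (-0.3233) and CONV 7 (-0.2124) stayed. Dose rate and library preparation or RNA quality cannot be told apart as the source, since the labels give no preparation batch. The slope differed by 0.215 between FLASH and CONV (exact permutation p = 0.1035), with SDs of 0.1978 and 0.2111 within them. Control 6 (-0.4103), which received no radiation, was nearly as steep as CONV 6. The rRNA-like gene Gm42418 held 0.906% of counts in control 6 and 1.561, 0.868 and 0.602% in CONV 2, CONV 6 and FLASH 1. It held 0.233 to 0.623% in the other libraries. What this share marks was not tested.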

How the results depend on the processing

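The length and GC offset and the sets without control 6, CONV 6 and FLASH 1 or without FLASH 1 and FLASH 2 were chosen after seeing the data. No gene called in any of the 3 comparisons passed in the opposite direction under any alternative. Where no reason is given below, the cause was not tested.

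A log2 fold change over 1 left 1970, 3198 and 1347 genes in CONV against control, FLASH against control and FLASH against CONV, by its construction. In FLASH against CONV 1569 genes passed with replicate number as a block and 6072 with 1 surrogate variable, against 3217. The 13 pairs of libraries with 1 number correlated with a median of -0.085, against 0.0232 for other pairs. They ranged from -0.3697 to 0.6925, so pairing by number was not seen as a rule but is not excluded. CONV against control gave 1869 (without CONV 6) to 6493 genes (without control 6).

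With an estimated correlation camera called 1, 1 and 0 lists, and exact permutation called 0 in FLASH against CONV, where a single list at the smallest p that 792 splits can give adjusts to 0.0530 over 42 lists. Several lists at that p together could have passed. Endothelial genes in CONV against control had camera adjusted p from 0.07688 (without control 6) to 0.8808 (without control 2, as higher), and in FLASH against control from 0.01887 (without control 2) to 0.8632 (without control 6, as lower) among single libraries left out, and 0.9906 without the steepest-length libraries. Endothelial activation genes in FLASH against control ran from 0.2632 (without control 2) to 0.9789 (without FLASH 7), and 0.8694 without the steepest-length libraries.

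Clu changed sign most often. Its log2 fold change in CONV against control was 0.9115 with limma-voom, 0.9457 with limma-trend, 0.9149 with the block and 0.6784 with the surrogate variable, and from -0.4374 (without CONV 3) to 1.3212 (without control 2). For Clu, FLASH vs control, it was 0.0203 on the authors' genes, 1.0508 with limma-voom, 1.0976 with limma-trend, 0.9805 with the block and 0.7627 with the surrogate variable, and from -0.3354 (without control 6) to 1.3689 (without control 2). In FLASH against CONV it was 0.0342 with DESeq2 size factors and with DESeq2, 0.0063 without the filter, 0.05 on the authors' genes, 0.1393 with limma-voom, 0.1519 with limma-trend, 0.0186 with 2 groups, 0.0656 with the block, 0.0843 with the surrogate variable and 0.0634 with the offset, and from -0.235 (without CONV 7) to 0.3419 (without CONV 3).

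For Pecam1, FLASH vs control, the log2 fold change was 0.0264 with limma-trend and 0.1547 with the surrogate variable, and from -0.4517 (without control 6) to 0.3449 (without control 2). For Kdr, FLASH vs control, it was 0.2605 with the surrogate variable, and from -0.7982 (without FLASH 7) to 0.1457 (without control 2). For Plvap, FLASH vs control, it was 0.1136 with limma-voom, 0.1455 with limma-trend and 0.227 with the surrogate variable, and from -0.3517 (without control 6) to 0.4395 (without control 2). Vwf was at 0.0162 with the surrogate variable.

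The radiation score difference of 0.3787 was 0.6223 on risen genes, 0.3868 without the mitosis, DNA replication and p53 lists, 0.4627 with the offset and 0.445 without the steepest-length libraries, all past the threshold. It was 0.2352 on all genes with an adjusted p under 0.05 (exact permutation p = 0.0947), -0.1351 on fallen genes (0.508), 0.3082 without FLASH 1 and FLASH 2 (0.151) and 0.3763 with DESeq2 size factors (0.0543), none of these 4 past it, and 0.3123 (without CONV 3) to 0.5757 (without CONV 6). Agreement of the responses was 0.6186 with the controls split, 0.7078 at a mean of at least 10 CPM, and from 0.697 (without CONV 6) to 0.7639 (without control 6).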

Other observations

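The test of length and GC bias below was chosen only after the result was seen.

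Lists that camera called in no comparison included neutrophil and enteroendocrine genes. Of 8 measured neutrophil genes, 5 were higher and 1 lower in FLASH than in control (camera adjusted p = 0.0738). Of 17 enteroendocrine genes, 6 were higher and 0 lower in FLASH than in CONV (camera adjusted p = 0.0584).

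In FLASH libraries 12 glucocorticoid and fasting genes, chosen because they were seen high in FLASH, among them Fkbp5, Zbtb16, Sgk1, Pdk4 and Tsc22d3 (1.29 ± 0.25), were higher than in CONV, with a mean log2 CPM of 7.49 ± 0.81 (SD, n = 7) against 4.78 ± 0.44 (n = 5) and 3.87 ± 0.22 in controls (n = 6). Being chosen this way, they are no test of whether the pattern holds. With the length and GC trend removed 12 of these 12 genes passed. Genes picked for large differences were likely to pass, so this only argues against that trend as their whole source. With Dbp minus Arntl or a distal minus proximal score in the model, 98.442% and 102.508% of the difference was left. Neither score differed clearly between FLASH and CONV (exact permutation p = 0.681 and 0.674), so neither could take much away. Time of day and position along the intestine are argued against only as far as these scores mark them. Another 10 glucocorticoid receptor targets were listed after the pattern was seen but before their own values were, except that Dusp1 belonged to the immediate early and heat shock list tested earlier. Their mean log2 CPM was higher by 0.79 in FLASH than in CONV (exact permutation p = 0.02652), and by 0.53 than in control (exact permutation p = 0.0962), while CONV differed from control by -0.26 (exact permutation p = 0.325), with Usp2 (0.91 ± 0.16), Irs2 (2.09 ± 0.37) and Dusp1 (1.35 ± 0.34) passing between FLASH and CONV and 7 not. Tsc22d3 and these 3 genes are named after their values were seen. The permutation on the 10 targets was not repeated with the length and GC trend removed, where 4 of them passed as higher between FLASH and CONV. Stronger glucocorticoid receptor activity in FLASH mice is a candidate explanation. Handling, anaesthesia, feeding and sickness of the mice are not in the labels and stay open beside dose rate.

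Other splits of the same libraries tested whether the counts could arise by chance. For genes, 1 of 60 splits drawn, the real one, gave as many calls in each comparison. It gave 3615 calls against 667 in the highest other split for CONV against control. For FLASH against control it gave 6135 against 3510, and for FLASH against CONV 3217 against 1225. A share under 1 in 60 could not be seen, and splits that mix the groups raise the spread. The gene counts therefore argue against chance without excluding it. For lists, 27, 8 and 28 of 60 splits gave as many camera calls, with 17, 23 and 11 real calls against 24, 28 and 20 in the highest other split. Chance cannot be excluded for the number of lists called.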
